A study of Mus musculus with 47 samples.

How the data were processed

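RNA was sequenced from 3 sorted mammary epithelial fractions of ovariectomized FVB mice. Per the labels, the fractions were luminal mature cells (LM), luminal progenitor cells (LP) and mammary stem cells (MSC), sorted by flow cytometry. The animals had received a sham treatment, estradiol with progesterone (EP), EP with telapristone acetate (EP+TPA) or EP with mifepristone (EP+RU486) for 14 days. Telapristone and mifepristone are steroidal antagonists of the progesterone receptor. The doses are not stated in the labels. The 47 libraries came from 20 mice and formed 12 groups of 3 or 4 separate mice. Libraries were made from full-length amplified complementary DNA and read as pairs on 1 Illumina instrument type.

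Per the submitters' processing notes, STAR, Cufflinks, DESeq2 and the mouse build mm9 were used, with neither versions nor the order of the steps. The values deposited by the authors had the scale of FPKM (mapped fragments scaled for transcript length and library depth), although they were described as read counts. They were not whole numbers, and they carried a further adjustment by gene that the notes do not mention. Within each of 3 sets of libraries, each gene's values had been shifted and rescaled so that the means of the sets were almost equal, with values under 0 set to 0. Over 11025 genes with values above 1 in every set, the median absolute log2 deviation of a set's mean from the mean of the sets was 0.0407. Pairs of libraries of the same set shared 1382 to 6495 identical positive values, and pairs of different sets shared 0. Set 1 held the 15 LM libraries. Set 2 held the 16 LP libraries and 6 MSC libraries, from mice 305, 306, 308, 322, 323 and 324. Set 3 held the other 10 MSC libraries. The sets were inferred from the values and not from the labels.

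This adjustment fixed what could be compared. A difference in mean level between sets had been removed, so LM was not compared with LP or MSC, and differences of treatment effects between LM and the other fractions were not tested. MSC and LP were compared only within set 2. Fits of MSC carried a term for the set. The number of reads behind a value is unknown, and neither counting intervals nor detection limits are given. A value listed at 0 may stand for a level under the adjustment's shift and was not read as absence.

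A quasi-likelihood test of counts with trimmed mean scaling had been planned before the data were examined. Values that are not counts do not suit that test, so limma 3.58.1 in R 4.3.3 was used on log2(value + 1). The fit had empirical Bayes moderation with a trend and robust estimation, and all 4 treatment groups of a fraction shared 1 fit. Values as deposited were found to differ in overall level between libraries within a set. They were therefore rescaled within each set by median-ratio factors of 0.529 to 1.317, applied to the part of a value above the gene's shared lowest value in the set. This scaling was chosen after results without it had been seen, and results without it are given among the alternatives. Genes were kept when at least 3 libraries had a value of 1 or more and at least 3 lay above the shared lowest value of their set. Of 22007 gene symbols, 27 resembled calendar dates and were left out, 21980 were used, and 21191 of all symbols matched a current mouse symbol. P values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and an adjusted p under 0.05 counted as a change. Folds are differences of mean log2(value + 1), which compresses folds of genes near 0. The shift by gene alters the size of folds as well, and it differed between sets. Sizes of folds in LM and LP are therefore not comparable. Levels are rescaled FPKM as mean ± SD over mice.

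Tests of 25 gene lists, fixed before the data were examined, used camera in limma with the correlation among members estimated for each list. Camera asks whether a list moved more than other genes did. Results with a preset correlation of 0.01 and with fry, which asks whether members moved on balance in 1 direction, are given beside it. Adjustment was over lists within a comparison. The lists covered proliferation, targets and coregulators of steroid receptors, markers of 3 epithelial fractions and of 7 other cell types, milk, signalling, stress, lipid and ribosomal genes. List values per library are mean log2 values over members, centred on the fraction's libraries of the same set.

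An EP-response score per library was the mean log2 value of 100 genes higher in EP than in sham minus that of 100 lower genes, those with the smallest p. For an EP or sham library the genes were chosen by a fit without it, and the score was centred on sham libraries. Scores were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over 12 comparisons. The smallest p such a test could give was 0.0571 for 3 mice against 4 and 0.0286 for 4 against 4. Intervals of 95% come from inverting that test. The permutations shuffled finished scores and did not repeat the choice of genes, which used the EP and sham labels. Antagonist libraries were scored on genes chosen from all EP and sham libraries, and a sham library was part of the mean it was centred on. The p values of the scores are therefore approximate. Scores of an antagonist against sham lay outside the 12 comparisons, and their p values are unadjusted. Correlations across libraries used permutation tests with 100000 resamples.

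Genes are named by a rule fixed beforehand. In each treatment comparison these were the 8 with the smallest p in each direction among changed genes with an absolute log2 fold of at least 1, an assigned name and no overlap between the groups. Where fewer than 3 passed, the 3 smallest p were taken. Up to 4 changed members of each list and 16 receptor, paracrine and lineage genes (among them Pgr, Esr1, Prlr, Tnfsf11, Wnt4, Areg, Calca, Mki67, Csn2, Elf5, Kit, Lgr5, Krt14 and Krt18) were added. Pecam1 and Cdh5 in MSC against LP were chosen after their values had been seen. The text gives 242 values of 120 such genes and leaves the others to the summaries.

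The procedure was tested on simulated data with 100 changed genes at each of 2 log2 folds per comparison. At a log2 fold of 1, 45% to 58% were recovered in LM, 72% to 87% in LP and 35% to 47% in MSC. At a log2 fold of 2, 86% to 98%, 95% to 98% and 71% to 81% were recovered in the same order. In MSC against LP 85% and 96% were recovered, and in the difference of EP effects 12% and 70%. Between 2 and 12 unchanged genes were called per comparison. The simulated noise was independent between genes and libraries, without correlated genes, outlying libraries or varying cell makeup. These figures therefore need not carry over to the real libraries.

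Within a fraction each mouse gave 1 library, so no pairing applied. The 6 mice with MSC and LP libraries in set 2 are the same animals by their label, and the mouse was used as a block in an alternative fit. The correlation of a mouse's MSC and LP residuals was -0.217, 0.219, 0.347 and 0.236 for mice 306, 308, 322 and 324, and could not be computed for 305 and 323, each the lone MSC library of its group in the set. Alternatives were the scaling, the pseudocount, the filter, library weights, fits of 2 groups only, a term for the mouse number range (above or below 320), terms and subsets for MSC, and leaving out each library in turn. Other software versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and statmod 1.5.0.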

Results

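Transcripts were measured in 47 libraries of sorted mammary epithelium from ovariectomized FVB mice after 14 days of treatment. There were 15 LM, 16 LP and 16 MSC libraries. Each fraction had 4 libraries per treatment (sham, EP, EP+TPA and EP+RU486), except for LM EP with 3. Absolute read depth is unknown, since the values carry no counts. The total of the values ran from 281713 to 349658 in LM, from 298037 to 358815 in LP and from 218245 to 356592 in MSC. Genes with a value above 1 numbered 10148 to 11179, 10212 to 11333 and 9413 to 11137 in the same order. The 10 highest genes held 6.46% to 13.1% of the total in LM, 7.05% to 13.04% in LP and 5.53% to 12.1% in MSC. Relative to the other libraries of their set, depth was estimated from the steps that single reads make among low values, at 0.790 to 1.16 times in LM, 0.683 to 1.14 in LP and 0.877 to 1.78 in MSC.

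The study's treatments address how ovarian hormones act on each epithelial fraction and how far a progesterone receptor antagonist undoes that action. The comparison of EP with sham in LM, the fraction that carries most of the hormone receptors, gave 2329 changed genes of 11885 tested, 1215 higher and 1114 lower (1665 and 754 without rescaling). The kinase Fam20c, which phosphorylates secreted proteins including caseins, rose from 0.531 ± 0.242 (SD, n = 4) to 15.5 ± 2.34 (n = 3), a log2 fold of 3.43 (SE 0.30, adjusted p 6.56e-06). Socs2, a feedback inhibitor of prolactin and growth hormone signals, rose by 3.05 (SE 0.27, adjusted p 6.56e-06). The prolactin signal carriers Stat5a and Stat5b rose by 4.53 (SE 0.58, adjusted p 0.000364) and 1.71 (SE 0.23, adjusted p 0.000284); Stat5a reached 79.4 ± 27.4. The paracrine progesterone mediator Tnfsf11, which encodes RANKL, was listed at 0 in all 4 sham libraries and at up to 40.7 in the 3 EP libraries, with a mean of 23.3 ± 17.9 (adjusted p 0.000579).

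Other genes that rose in LM with EP were the receptor cochaperone Fkbp5 (log2 fold 2.12, SE 0.27, adjusted p 0.000194), the cytokine Il34 (2.34, SE 0.24), the estrogen-regulated growth inhibitor Rerg (2.87, SE 0.42), the desaturase Scd2 (3.87, SE 0.61), the ETS factor Etv5 (2.01, SE 0.35) and the chaperone Pdia6 (1.60, SE 0.23). Khdrbs3, Angptl7 and Slc5a8 were listed at 0 in 4 of 4 sham libraries and reached 42.5 ± 16.5, 34.0 ± 4.09 and 14.3 ± 11.7 with EP (n = 3). Among genes that fell, the estrogen receptor gene Esr1 went from 23.8 ± 6.85 (n = 4) to 5.10 ± 5.34 (n = 3), a log2 fold of -2.33 (SE 0.42, adjusted p 0.00232). Dnajc12 fell by 3.80 (SE 0.29, adjusted p 1.08e-06) and the alarmin Il33 fell by 4.70 (SE 0.42, adjusted p 9.28e-06). Declines were also measured for the estrogen receptor cofactor Cited1 (log2 fold -4.84, SE 1.04), the growth factor receptor Fgfr2 (-2.92, SE 0.52), Wnt7b (-2.80, SE 0.47) and Lgr5 (-1.94, SE 0.37). The pattern receptor Cd14 fell from 291 ± 193 to at most 16.4, and Clu, Cebpd and Lurap1l fell by 2.30, 2.25 and 2.31 (SE 0.52, 0.44 and 0.47). Fam25c, Upk3a, lactoferrin (Ltf) and Btn1a1 were listed at 0 in all 3 EP libraries, against 281 ± 63.3, 75.8 ± 39.3, 2549 ± 1439 and 70.0 ± 45.7 in sham (n = 4). Areg and Prlr did not pass, with log2 folds of 2.81 (SE 1.39, adjusted p 0.176) and -1.39 (SE 0.95, adjusted p 0.336); the fold of Areg was 1.71 without EP mouse 311. Prlr passed with the 2 groups only (adjusted p 0.0409) and with library weights (0.0172), and Fgfr2 lost its call with a pseudocount of 0.1 (0.0723).

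Of 48 measured proliferation genes in LM, 45 rose with EP over all genes and 47 adjusted over the list alone, with a median log2 fold of 2.07. Top2a reached 6.76 ± 2.28 from 0 in 3 of 4 sham libraries, Racgap1 rose by 3.07 (SE 0.41), Prc1 by 2.90 (SE 0.38) and Mki67 by 1.08 (SE 0.25), and Cdk1 was listed at 0 in all sham libraries and at 6.08 ± 3.14 with EP. Of 54 ribosomal protein genes 30 rose (39 adjusted over the list alone), among them Rps18 from 369 ± 51.1 to 685 ± 40.7. Genes with near-identical copies, such as these and the caseins, are uncertain in any fold given here. Of 22 luminal progenitor markers 8 fell and 1 rose, and of 28 milk and alveolar genes 7 fell and 3 rose. Over the list alone 13 and 9 fell. Milk genes had a median of 0.01 and a mean of -1.09, and luminal mature markers a median of -0.44 and a mean of 0.29 with 3 members in each direction. Genes of the unfolded protein response rose in 6 of 23 and fell in 3, and immediate early and dissociation stress genes fell in 3 of 26. Wnt pathway genes rose in 6 of 31 and fell in 2, with a mean whose sign turned without rescaling. Interferon response genes fell in 3 of 26 and rose in 1, and cholesterol and fatty acid synthesis rose in 2 of 27 and fell in 3. With the estimated correlation camera gave no list an adjusted p under 0.953 in this comparison. With the preset correlation proliferation had an adjusted p of 6.36e-30, and by fry 0.00449. The number of changed genes rested on few mice and was 907 without EP mouse 327, 1119 without EP 306, 1512 without sham 310 and 1538 without sham 326.

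**Figure D1:**
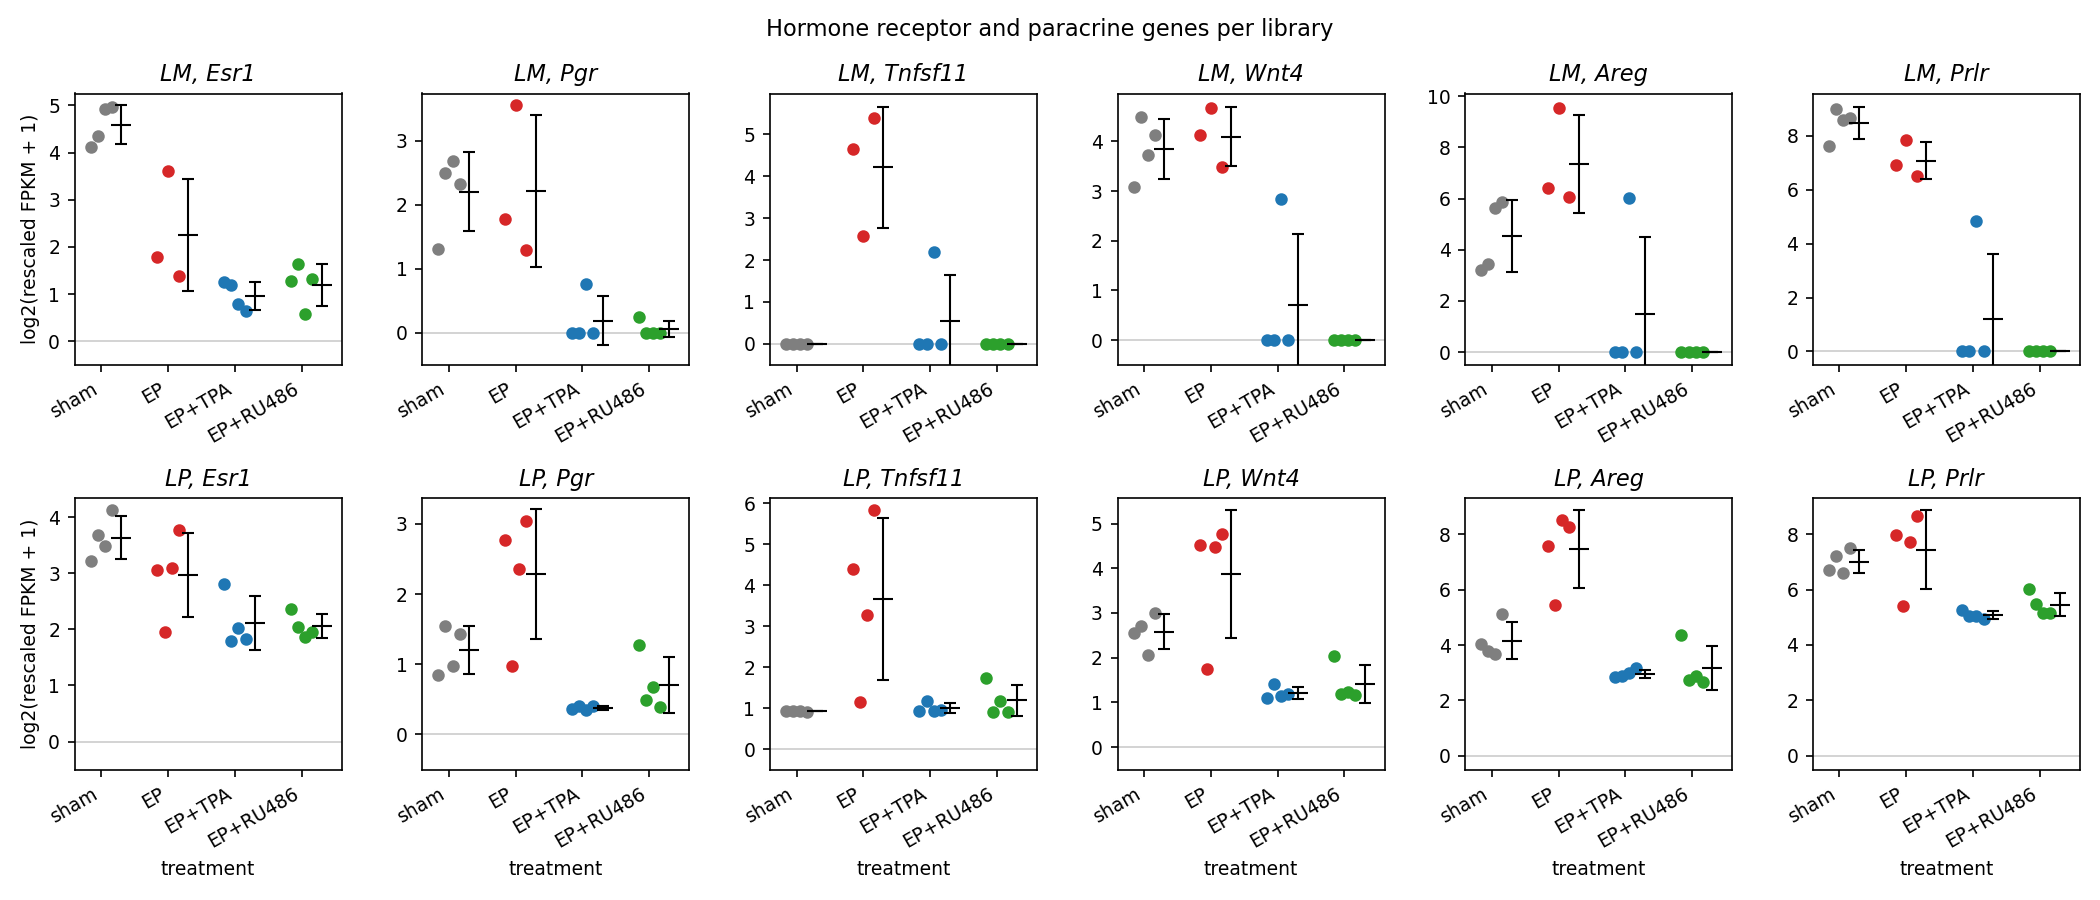
Levels of Esr1, Pgr, Tnfsf11, Wnt4, Areg and Prlr as log2(rescaled FPKM + 1) in LM and LP by treatment, with a point per library and bars for mean ± SD. In LM all 4 RU486 libraries are at 0 for Tnfsf11, Wnt4, Areg and Prlr.

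EP+TPA was compared with EP to find what telapristone removes from the hormone response. In LM 539 genes changed, 155 higher and 384 lower. The prolactin receptor Prlr was listed at 0 in 3 of 4 TPA libraries and at 27.5 in that of mouse 332, against 146 ± 73.7 with EP (n = 3, adjusted p 0.00640). The pioneer factor Foxa1, which opens chromatin for the estrogen receptor, stood at 0 in the same 3 and at 3.31 in mouse 332, against 23.6 ± 16.6 (adjusted p 0.00369). The paracrine genes Tnfsf11 and Wnt4 had the same form, with 3.59 and 6.14 in mouse 332 against 23.3 ± 17.9 and 17.1 ± 7.23 with EP (adjusted p 0.00486 and 0.00661). Pgr, at 4.86 ± 5.08 with EP, was at 0 in 3 and at 0.695 in mouse 332 (adjusted p 0.0179). Falls were measured for Il34 (log2 fold -2.06, SE 0.24), the riboflavin transporter Slc52a3 (-2.49, SE 0.30), Bdnf (-2.42, SE 0.31), the death receptor Tnfrsf21 (-2.04, SE 0.27), Fkbp5 (-1.42, SE 0.27) and the growth factor receptor Erbb2 (-1.30, SE 0.23). Angptl7, Stc2 and Fgfr2 were at 0 in 3 libraries and at 1.52, 22.2 and 3.67 in the highest.

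Genes that rose in LM with TPA were Trib2 (log2 fold 1.47, SE 0.20), the palmitoyltransferase Zdhhc14 (2.88, SE 0.44), the tetraspanin Tspan33 (3.31, SE 0.50), Lurap1l (2.80, SE 0.47), the inflammatory caspase Casp4 (1.61, SE 0.28), Cebpd (2.45, SE 0.44), the elongase Elovl6 (1.28, SE 0.25) and Cd14 (5.96, SE 1.19). Of 24 luminal mature markers 12 fell (16 adjusted over the list alone, where 1 rose), with a median of -2.10. Of 22 luminal progenitor markers 6 rose (16 over the list alone), with a median of 2.55, and of 28 milk genes 6 rose and 1 fell. Proliferation had a median of -1.14, yet 3 of 48 members fell over all genes and 39 over the list alone. Of progesterone and estrogen receptor targets 6 of 28 and 6 of 22 fell and none rose over all genes; estrogen targets had a median of 0.13 and a mean of -0.93. Endothelial markers were higher in fold in this fraction, with a median of 0.63 and 0 of 20 past the threshold, and so were skeletal muscle and red blood cell markers (medians 1.26 and 1.46; 0 of 11 and 0 of 4). With the estimated correlation the adjusted p was 0.269 for luminal mature and 0.304 for luminal progenitor markers, and by fry 0.00294 and 0.0133.

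The count in LM turned on the library of mouse 332, without which 2220 genes changed, 1135 higher and 1085 lower. Without it 42 of 44 proliferation genes fell (median -1.54), 12 of 23 luminal mature markers fell and 1 rose (median -2.21), 15 of 22 luminal progenitor markers rose (median 3.11) and 11 of 28 milk genes rose and 2 fell. Endothelial markers rose in 15 of 20 without it, with a median of 0.96. It was 186 without TPA 336, 212 without TPA 312, 237 without TPA 328, 260, 261 and 352 without EP 306, 311 and 327, and 2 when only these 2 groups were fitted, where all genes named above except Angptl7 lost their call. Cd14 lost its call without EP 306 (adjusted p 0.0702), EP 327 (0.0629) and TPA 312, 328 or 336 (0.0574, 0.0541 and 0.0624), and Pgr without TPA 312, 328 or 336 (0.0598, 0.0567 and 0.0642).

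Mifepristone, an older antagonist that also binds the glucocorticoid receptor, was compared with EP in the same way. In LM 2141 genes changed with RU486, 1055 higher and 1086 lower (731 and 1685 without rescaling). Foxa1, Tnfsf11, Prlr, Wnt4, Stc2, Angptl7 and Areg were listed at 0 in all 4 RU486 libraries, with adjusted p between 2.61e-08 and 0.00549; with EP the means of Stc2 and Areg were 142 ± 136 and 300 ± 389 (n = 3). The collagen hydroxylase P4ha2 fell from 44.8 ± 21.9 to 0.557 ± 0.339 (n = 4), a log2 fold of -4.80 (SE 0.54, adjusted p 0.000471). Fam20c fell by 2.69 (SE 0.30), Il34 by 2.38 (SE 0.24), Slc52a3 by 2.92 (SE 0.30), Fgfr2 by 3.55 (SE 0.52), Fkbp5 by 1.45 (SE 0.27) and Pgr by 2.15 (SE 0.43). The neutrophil lipocalin Lcn2, made by progenitor cells, rose from 250 ± 208 to 3315 ± 413 (log2 fold 4.03, SE 0.91, adjusted p 0.0112). Milk fat globule genes Mfge8 and Xdh rose by 3.33 (SE 0.58) and 4.03 (SE 0.66), Cd14 by 7.15 (SE 1.19), Aldoc by 3.36 (SE 0.60), Zdhhc14 by 3.24 (SE 0.44), Lurap1l by 2.77 (SE 0.47), Cebpd by 2.40 (SE 0.44), Lbp by 2.34 (SE 0.46) and Isoc1 by 2.24 (SE 0.30). Smaller rises were those of Dusp6 (1.83, SE 0.33), Casp4 (1.80, SE 0.28), Runx2 (1.67, SE 0.25) and Elovl6 (1.52, SE 0.25).

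Of 48 proliferation genes in LM 44 fell with RU486 (45 adjusted over the list alone), with a median of -1.44; Melk, Top2a and Ndc80 fell by 2.03, 1.95 and 1.5 (SE 0.41, 0.41 and 0.30). Luminal mature markers fell in 15 of 24 and rose in 1, with a median of -2.21, and luminal progenitor markers rose in 15 of 22 and fell in 1, with a median of 2.96 (19 fell and 15 rose over the lists alone). Milk genes rose in 13 of 28 and fell in 2. Progesterone receptor targets fell in 8 of 28 and rose in 2, and estrogen receptor targets fell in 7 of 22 and rose in 1, the latter with a median of 0.05 and a mean of -1.08. Notch pathway genes rose in 8 of 22 and fell in 3, and genes of the EGF family rose in 5 of 18 and fell in 7. Basal markers rose in 7 of 30 and fell in 1 (median 0.42), endothelial markers passed in 0 of 20 and in 11 adjusted over the list alone (median 0.82), and immune markers rose in 0 and fell in 1 of 16 (median 0.24, with a test direction of lower that turned without rescaling). Camera with the estimated correlation gave adjusted p values of 0.293 for luminal mature and 0.394 for luminal progenitor markers, and fry gave 0.000675 and 0.00392. The count was 1297 without EP mouse 327, 1396 without EP 306 and 1417 without RU486 mouse 333.

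**Figure D2:**
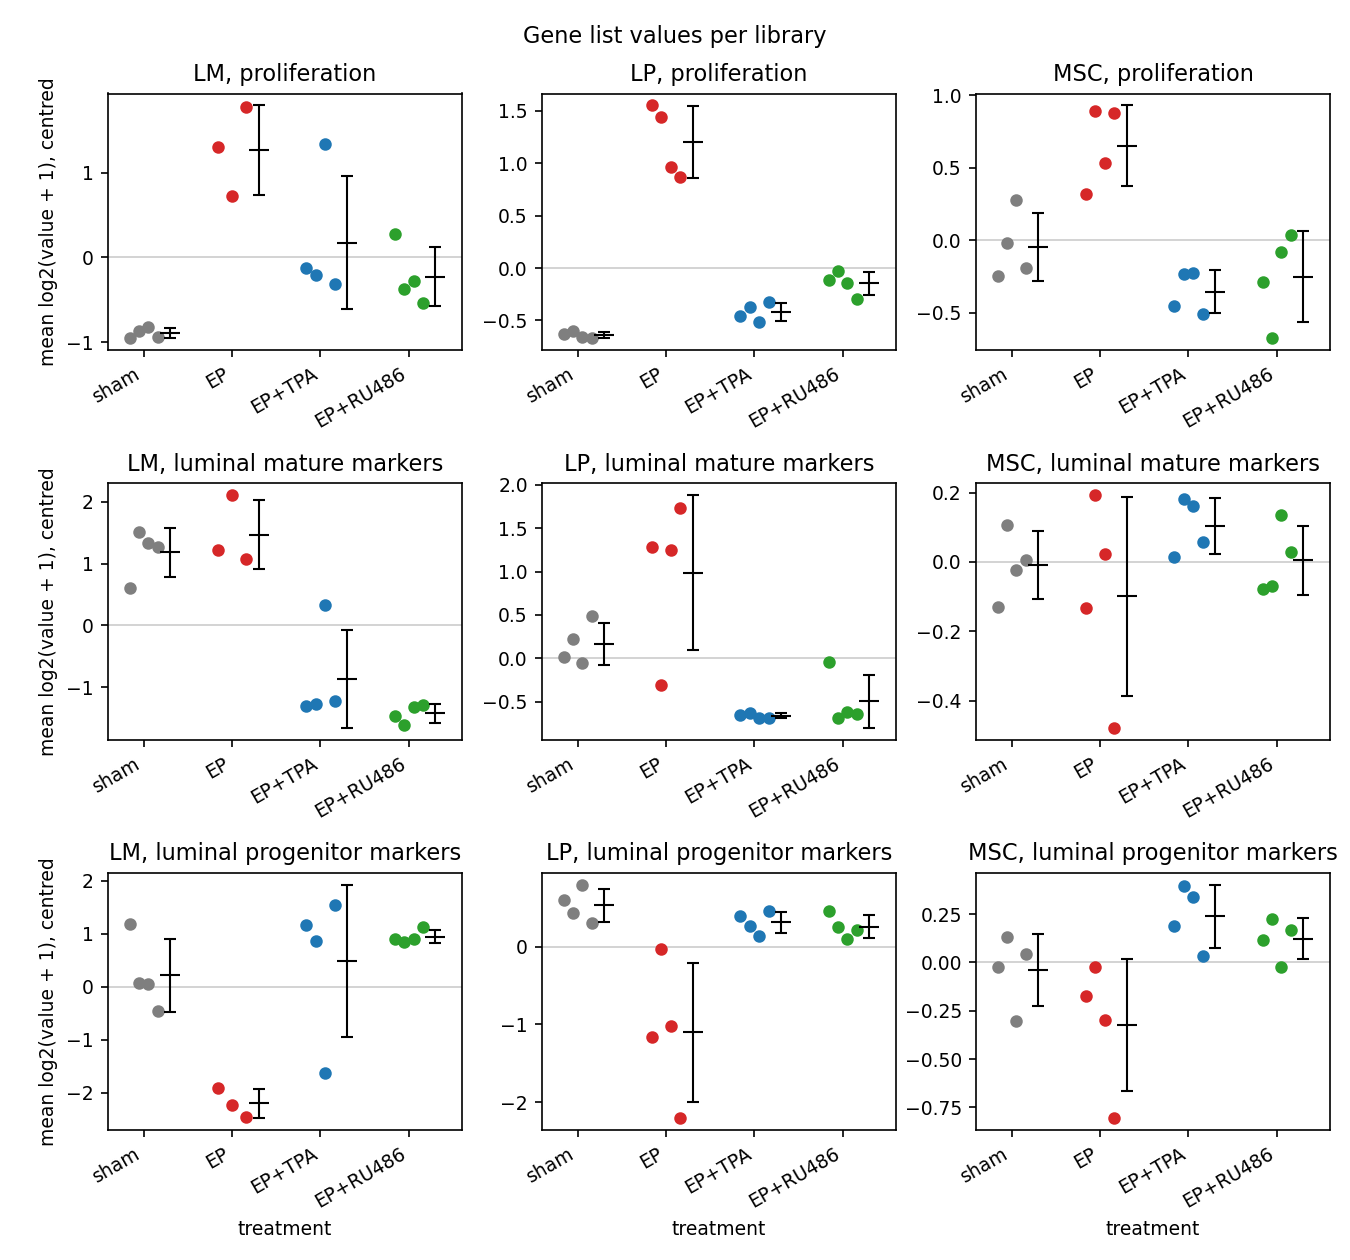
Mean log2 values of proliferation genes, luminal mature markers and luminal progenitor markers per library in LM, LP and MSC, centred within each set of libraries, with bars for mean ± SD by treatment. Luminal mature values of LM lie between -1.61 and -1.22 with an antagonist, except for TPA mouse 332 at 0.331, and between 1.07 and 2.11 with EP.

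The 2 antagonists are related steroids and were compared directly at the same 14 days, at doses the labels do not give. In LM limma called 0 genes between TPA and RU486, with 1580 at an unadjusted p under 0.05 and a smallest adjusted p of 0.329. Among the smallest p values were those of the splicing factor Srsf7 (log2 fold 0.78, SE 0.16), AW112010 (2.73, SE 0.53), the cyclin Ccnf, at 0 in 4 RU486 libraries and 0.207 to 2.40 with TPA, and Chdh (-1.22, SE 0.25). Without TPA mouse 328 there were 4 calls, with Ccnf and AW112010 at adjusted p 0.00916 and 0.0269, and with a pseudocount of 0.1 there was 1 call, Ccnf, at 0.0412. Median log2 folds were 0.45 for luminal mature markers, -0.73 for luminal progenitor markers and 0.39 for proliferation, and no member passed over all genes. A missed threshold does not show that both drugs acted alike.

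Each antagonist was also set against sham in LM. No group had estradiol alone or an antagonist alone. A difference from sham therefore cannot be split into remaining hormone action and an effect of the drug itself. There were 1924 changed genes with TPA (801 higher, 1123 lower) and 2589 with RU486 (1220 higher, 1369 lower). Khdrbs3 and Slc5a8, at 0 in sham, stood at 105 ± 22.8 and 52.7 ± 19.5 with TPA and at 108 ± 12.1 and 56.6 ± 4.95 with RU486 (n = 4 each). These means lay above those with EP, so they are not a remainder of the EP level. Fam25c and Upk3a were at 0 in all antagonist libraries. Esr1 lay below sham by log2 folds of -3.62 and -3.39 (SE 0.39 each, adjusted p 3.42e-05 and 4.20e-05), Dnajc12 by -4.31 and -4.50 (SE 0.26 each) and Fgfr2 by -6.01 and -6.46 (SE 0.48 each). The molybdopterin gene Mocs2 rose by 2.50 and 3.08 (SE 0.25 each). Prlr, at 375 ± 131 in sham, was at 0 in 3 of 4 TPA and 4 of 4 RU486 libraries. Ribosomal protein genes rose in 42 of 54 with TPA and in 47 with RU486 (50 and 51 adjusted over the list alone), among them Rpl3 by 0.88 and 1.24 (SE 0.15 each) and Rps7 by 1.16 and 1.39 (SE 0.18 each). Luminal mature markers fell in 13 and 16 of 24 and rose in 1. Luminal progenitor markers rose in 5 of 22 with each drug and fell in 0 and 1, with medians of 0.00 and 0.98, and without mouse 332 rose in 7 with TPA with a median of 1.12. Endothelial markers were higher in 0 and 1 of 20, and in 8 with TPA without mouse 332 (14 over the list alone), and their mean value lay above sham with RU486 by 0.524 (exact p 0.0286, adjusted 0.129). With the estimated correlation no list had an adjusted p under 0.341 against sham, and ribosomal protein genes had 0.667 and 0.553. Proliferation genes stayed above sham in 19 and 7 of 48, or 31 and 0 adjusted over the list alone, and without mouse 332 in 15 of 44 with TPA, or 18 over the list alone. Steroid receptors and coregulators fell in 4 of 17 and rose in 1 with each drug. The counts were 1089 (TPA) and 1662 (RU486) without sham mouse 326, and 1215 and 1704 without sham mouse 310.

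In LP, the fraction held to contain alveolar precursors, EP against sham changed 3728 of 11418 genes, 1908 higher and 1820 lower (3945 and 949 without rescaling). The replication factors Uhrf1 and Mcm2 rose by log2 folds of 2.89 (SE 0.18, adjusted p 5.17e-08) and 2.27 (SE 0.14, adjusted p 5.86e-08), Uhrf1 from 1.09 ± 0.0883 to 15.0 ± 4.65 (n = 4 each). Lactoferrin (Ltf) fell from 2187 ± 968 to 181 ± 52.1 and the casein gene Csn3 from 2848 ± 424 to 334 ± 406, log2 folds of -3.54 (SE 0.35) and -3.75 (SE 0.49). Of 47 proliferation genes 45 rose (46 adjusted over the list alone), with a median of 1.83; Stmn1, Birc5, Ccna2 and Mki67 rose by 2.95, 2.98, 2.45 and 1.16 (SE 0.18, 0.19, 0.18 and 0.11).

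Other genes that rose in LP with EP were the EGF receptor ligand Areg from 18.5 ± 10.4 to 228 ± 144 (log2 fold 3.30, SE 0.57, adjusted p 0.000559), the Wnt amplifier Rspo1 (3.11, SE 0.45), Calca (3.57, SE 0.93), Tnfsf11 (2.73, SE 0.65), the chemokine Cxcl15 (3.31, SE 0.60), the EGF family ligand Epgn (2.65, SE 0.42), Stat5a (1.75, SE 0.20) and Pgr (1.08, SE 0.34, adjusted p 0.0233). Besides milk genes, Cck (-3.18, SE 0.26), the calcium-binding annexin Anxa8 (-3.33, SE 0.25), Fgg (-2.62, SE 0.17), Ramp1 (-2.57, SE 0.15), Fam25c (-2.55, SE 0.16), the clock gene Per2 (-1.94, SE 0.16) and the metalloreductase Steap4 (-1.91, SE 0.14) fell. Milk genes fell in 15 of 28 and rose in 1, with Btn1a1 and Mfge8 at -3.52 (SE 0.38) and -1.91 (SE 0.28), and luminal progenitor markers fell in 16 of 22. Genes of the immediate early and dissociation stress list, which also respond to the handling of cells, fell in 20 of 26 (22 adjusted over the list alone; median -1.23), Maff and Jund by 2.27 and 1.60 (SE 0.24 and 0.18). Glucocorticoid receptor targets fell in 7 of 21 and rose in 1. Luminal mature markers rose in 9 of 24 and fell in 4 (median 0.67). Whether EP changed the makeup of the sorted LP fraction was not tested. The rises above, such as those of Areg and Pgr, therefore cannot be assigned to progenitor cells alone. Progesterone receptor targets rose in 9 and fell in 9 of 29 (their mean of 0.24 turned without rescaling). The RANK and NF-kB pathway fell in 8 of 21 and rose in 3, and fibroblast markers rose in 5 of 20 and fell in 1. Camera gave proliferation an adjusted p of 0.130 with the estimated correlation and fry gave 2.08e-07; no other list had an estimated p under 0.377. Pgr lost its call without sham 301, EP 306, sham 310, EP 322 or EP 327 (adjusted p 0.0656, 0.0764, 0.0628, 0.0517 and 0.0725) and with these groups alone (0.0856).

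In LP TPA against EP changed 2081 genes (871 higher, 1210 lower) and RU486 against EP 2398 (1055 higher, 1343 lower). Without rescaling the splits were 540 higher and 2172 lower, and 723 higher and 1963 lower. Areg fell to 6.82 ± 0.826 with TPA and 9.26 ± 6.85 with RU486 (n = 4 each), log2 folds of -4.49 and -4.29 (SE 0.57, adjusted p 8.89e-05 and 0.000156). The acute-phase gene haptoglobin (Hp) rose from 633 ± 154 to 2175 ± 212 and 2276 ± 283, log2 folds of 1.81 and 1.87 (SE 0.17). Uhrf1, Stmn1 and Birc5 fell by 2.53, 2.35 and 2.48 with TPA and by 2.05, 2.01 and 2.02 with RU486 (SE 0.18 to 0.19). With both drugs Pgr fell by 1.91 and 1.58 (SE 0.34), Foxa1 by 2.65 and 2.55 (SE 0.49), Prlr by 2.37 and 1.99 (SE 0.50), Wnt4 by 2.66 and 2.47 (SE 0.50), Tnfsf11 by 2.66 and 2.48 (SE 0.65), Rspo1 by 3.01 and 3.11 (SE 0.45), and the secreted Stc2 by 3.18 and 3.11 (SE 0.49).

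Milk genes went both ways in LP with both drugs. Csn3 rose by 3.56 and 3.48 (SE 0.49), to 2493 ± 236 with TPA and 2371 ± 376 with RU486 (n = 4 each), while Csn2 fell by 2.70 and 3.38 (SE 0.66). Ltf rose by 2.42 and 2.47 (SE 0.35), Lcn2 by 2.63 and 2.48 (SE 0.43), Anxa8 by 2.91 and 3.03 (SE 0.25), the protease Prtn3 by 2.33 and 2.55 (SE 0.18), Clca3a2 by 2.24 and 2.48 (SE 0.22) and Steap4 by 1.77 and 1.99 (SE 0.14). Proliferation genes fell in 45 of 47 with each drug, over all genes and adjusted over the list alone, with medians of -1.65 and -1.34. Luminal progenitor markers rose in 15 of 22 with each (17 over the list alone; medians 1.30 and 1.23). Luminal mature markers fell in 15 and 14 of 24 and rose in 1 (medians -1.76 and -1.61). Milk genes rose in 13 and 12 of 28 and fell in 2 and 5. Progesterone receptor targets fell in 13 of 29 with each and rose in 2 and 4, estrogen receptor targets fell in 8 of 22 and rose in 3, and Wnt pathway genes fell in 9 of 27 and rose in 5 and 7, with medians of 0.14 and 0.07, means of -0.13 and -0.07 and a direction that turned without rescaling. Notch pathway genes rose in 5 and 4 of 20 and fell in 3. Estrogen targets had medians of 0.02 and -0.06 and means of -0.58 and -0.51. Interferon response genes rose in 5 of 25 and fell in 2 with TPA, and rose in 1 and fell in 5 with RU486. Fibroblast markers fell in 5 of 20 with each drug, and rose in 0 and 1. With the estimated correlation camera gave proliferation adjusted p values of 0.0572 and 0.135, and no other list one under 0.379. The TPA count was 1340 without EP mouse 306. With only the compared groups fitted the TPA count was 901 and calls ended for Tnfsf11 with TPA and RU486 (adjusted p 0.0814 and 0.0832) and for Prlr with RU486 (0.0638).

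Between TPA and RU486 limma called 0 genes in LP, with 204 at an unadjusted p under 0.05 and a smallest adjusted p of 1. Interferon-induced genes had the smallest p values among those higher with TPA, namely Ifi27 (log2 fold 0.91, SE 0.18), the oligoadenylate synthetase Oas1g (0.94, SE 0.20) and Rtp4 (1.38, SE 0.33). Of 25 interferon response genes 0 passed over all genes and 12 were higher adjusted over the list alone, with a median of 0.60. The list had an adjusted p of 0.147 with the estimated and 5.68e-27 with the preset correlation, and 0.426 by fry. Mean proliferation values were lower with TPA than with RU486 by a difference of -0.272, with no overlap of the libraries (exact p 0.0286, adjusted 0.129). Leaving out any library gave 0 calls.

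Against sham, 612 genes were changed in LP with TPA (221 higher, 391 lower) and 1257 with RU486 (534 higher, 723 lower). Hp rose by 3.5 and 3.56 (SE 0.17 each, adjusted p 6.29e-09 and 4.79e-09). The secretoglobin Scgb3a1 rose by 3.93 and 4.59 (SE 0.32), Khdrbs3 by 2.30 and 2.39 (SE 0.13), the sulfotransferase Chst8 by 2.54 and 2.65 (SE 0.20) and the glycoprotein hormone gene Stc1 by 2.16 and 2.31 (SE 0.20). Fgg fell by 2.81 and 2.86 (SE 0.17), Cck by 2.71 and 2.96 (SE 0.26), Fam25c by 2.53 and 2.60 (SE 0.16), Ramp1 by 1.62 and 1.76 (SE 0.15), Maff by 1.90 and 2.29 (SE 0.24) and Esr1 by 1.52 and 1.58 (SE 0.32). With RU486 Mcm2 and Stat5a stayed above sham by 0.94 (SE 0.14) and 2.03 (SE 0.20), and proliferation genes were above sham in 13 of 47 with RU486 and 0 with TPA (19 and 0 adjusted over the list alone). Mean proliferation values lay above sham by 0.222 with TPA and 0.494 with RU486, each with an exact p of 0.0286 (adjusted 0.129) and no overlap of the libraries. Immediate early and dissociation stress genes lay below sham in 6 and 9 of 26, glucocorticoid receptor targets in 5 and 7 of 21, progesterone receptor targets in 7 and 6 of 29 with 1 above, and the RANK and NF-kB pathway in 1 and 3 of 21. With the estimated correlation no list had an adjusted p under 0.198 against sham. Counts for TPA were 333 without TPA 323, 337 without sham 310, 368 without sham 326 and 385 without TPA 328, and for RU486 they were 677 without sham 310, 723 without RU486 mouse 324, 745 without RU486 308 and 827 without sham 301. Without rescaling most calls were higher than sham, 443 of 686 with TPA and 1315 of 1744 with RU486.

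Most genes called in LM and LP moved the same way. Of 11327 genes tested in both fractions 1433 were called in both for EP against sham, 1430 in the same direction where independence gave 367. The 442 shared calls for TPA against EP and the 1385 for RU486 against EP all had the same direction, where independence gave 51.1 and 218. Most LM and LP libraries came from the same mice, and whether an effect differed between LM and LP was not tested.

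In MSC, the basal fraction, limma called 0 of 12187 genes in each of the 6 treatment comparisons. Genes at an unadjusted p under 0.05 numbered 659 for EP against sham, 857 for TPA against EP, 592 for RU486 against EP, 200 between the antagonists, and 407 and 416 for TPA and RU486 against sham. The smallest p values for EP belonged to the cohesion factor Dscc1 (log2 fold 0.94, SE 0.17), the chaperone Fkbp11 (1.21, SE 0.24) and Ccna2 (1.17, SE 0.24), each with an adjusted p of 0.437. For TPA they were Dscc1 (-1.16, SE 0.17), Racgap1 (-1.63, SE 0.24) and Glb1l2 (-1.68, SE 0.26) at 0.0568, and among genes with a positive fold Papln (1.09, SE 0.19) stood at 0.0809. For RU486 they were Glb1l2 (-1.59, SE 0.25), the serine synthesis enzyme Phgdh (-1.84, SE 0.31) and Cenpn (-1.05, SE 0.18) at 0.233. Without EP mouse 306 there was 1 call for EP against sham and there were 17 for TPA against EP, Dscc1 and Racgap1 at an adjusted p of 0.0366 and Glb1l2 at 0.0472 among them. Library weights gave 1087, 155 and 96 calls for EP against sham and for TPA and RU486 against EP.

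The proliferation list passed in MSC for both antagonists against EP, and these were the only lists to pass in the 12 comparisons of EP with sham and of the drugs with EP and each other. Its median log2 fold over 42 genes was -0.98 with TPA (adjusted p 0.0142) and -0.91 with RU486 (0.0162), and 0.71 for EP against sham (0.0592). No member passed over all genes, and adjusted over the list alone 35, 31 and 18 did. Mean list values ran from 0.317 to 0.887 in EP, -0.245 to 0.277 in sham, -0.508 to -0.224 with TPA and -0.677 to 0.0390 with RU486. The result weakened to 0.0647 (TPA) and 0.0708 (RU486) without EP mouse 311 and to 0.0802 (RU486) without EP 306. Both calls also ended without rescaling (0.0734 and 0.0836), with the 2 groups only (0.111 and 0.345), in set 3 only (0.112 and 0.147) and without the low Krt14 libraries (0.0522 and 0.0654). These were 4 of the 8 antagonist libraries, all in set 3, TPA 312 at 2.59 and TPA 328, RU486 313 and RU486 329 listed at 0, while Krt14 was at least 135 in every sham and EP library. Endothelial markers had median folds of -0.88 for EP against sham and 1.42 and 1.39 for TPA and RU486 against EP, and adipocyte and pericyte markers -0.87 and -0.90 for EP against sham, with no member past the threshold. Mean luminal progenitor values were above EP by 0.563 with TPA (exact p 0.0286, adjusted 0.129) and 0.446 with RU486 (exact p 0.0571, adjusted 0.151).

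**Figure D3:**
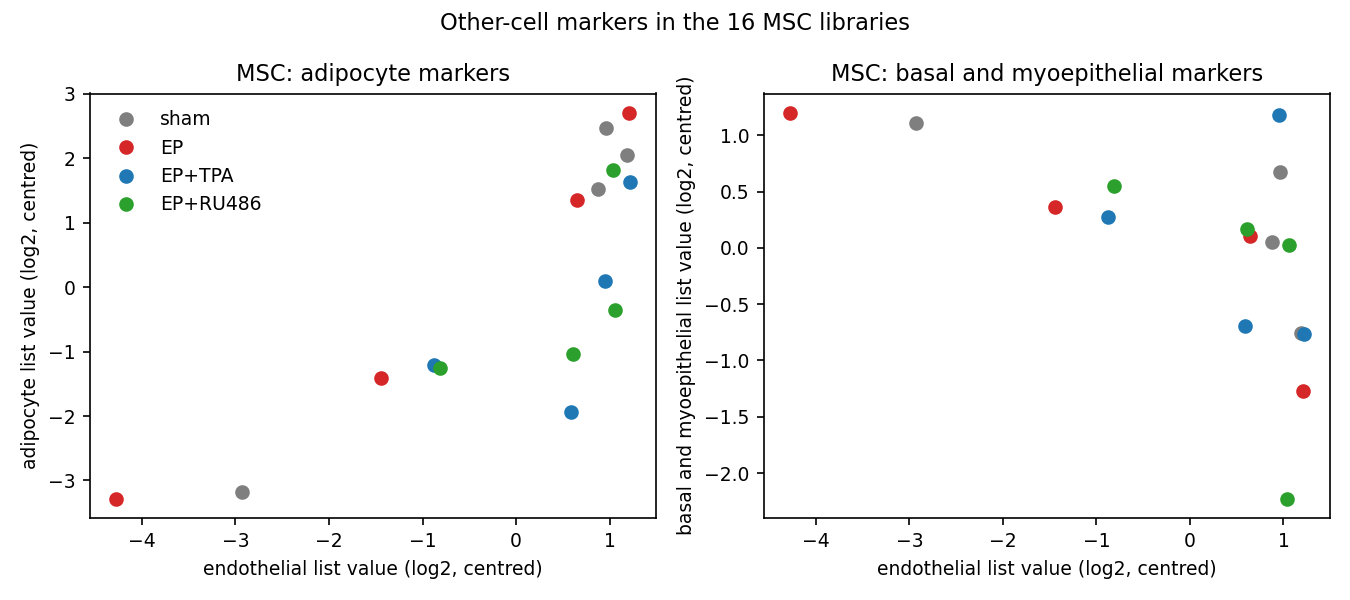
Endothelial list value of each MSC library on the x axis against its adipocyte and its basal list value, as mean log2 values centred within each set. EP mouse 327 lies lowest at -4.28 and sham mouse 326 next at -2.92.

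Among the 6 MSC and 16 LP libraries adjusted together, 6888 of 12254 genes differed, 3620 higher and 3268 lower in MSC. The basal keratin Krt14 was at 1590 ± 1079 in MSC (n = 6) and 72.9 ± 6.13 in LP (n = 16), a log2 fold of 4.24 (SE 0.28, adjusted p 1.53e-09). Contractile and matrix genes were higher in MSC, with Myl9 at 4.45 (SE 0.26), Myh11 at 3.79 (SE 0.17), Col17a1 at 3.31 (SE 0.18) and Sparc at 3.30 (SE 0.14), and the stem cell receptor Lgr5 was at 1.43 (SE 0.16). Lower in MSC were the luminal keratins Krt18 (-1.84, SE 0.19) and Krt19 (-2.12, SE 0.22), the alveolar factor Elf5 (-2.18, SE 0.23), Kit (-1.40, SE 0.26) and Csn3 (-3.30, SE 0.33). Basal markers were higher in 27 of 30 and lower in 1 (median 2.74, adjusted p 0.201 with the estimated and 1.5e-13 with the preset correlation), and luminal progenitor markers lower in 19 of 23 and higher in 1. Luminal mature markers were lower in 15 of 24 and higher in 1, and milk genes lower in 25 of 28 and higher in 2, with adjusted p values of 0.678 (luminal progenitor), 0.842 (luminal mature) and 0.201 (milk) with the estimated correlation. Markers of cells outside the epithelium were higher in MSC as well, endothelial in 17 of 20, adipocyte in 12 of 13, pericyte in 8 of 9 and fibroblast in 14 of 20 (2 lower), though each of these lists had an adjusted p of 0.842 with the estimated correlation. Skeletal muscle and red blood cell markers passed in 0 of 8 and 0 of 3. Pecam1 and Cdh5, made by blood vessels, were higher by 1.83 each (SE 0.34 and 0.39). The split by direction turned without rescaling, to 1789 higher and 7200 lower. With the mouse as a block in the 6 mice with both fractions 3461 genes differed, and without the block 3861, where Cdh5 lost its call (adjusted p 0.0665).

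For the difference in EP effect between MSC and LP limma called 233 genes, 78 with a higher and 155 with a lower fold in MSC, from a fit with 1 MSC sham library, that of mouse 305, assumed to vary like the other groups. Among the smallest p values were those of the myelin genes Prx (difference of log2 folds -2.85, SE 0.26) and Mag (-2.01, SE 0.20), and of Cldn19 (-2.57, SE 0.24) and Brinp3 (-1.72, SE 0.18). With the mouse as a block in 6 mice 0 genes passed, and without the block in the same mice 32, so a difference is not shown. The count was 1258 without MSC EP 306, 683 without LP EP 311, 640 without MSC EP 322 and 153 without LP sham 310.

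The EP-response score gave in 1 number the level of each library on genes that differed between EP and sham. With an antagonist it cannot be split into remaining hormone action, an effect of the drug itself and a change of cell makeup. In LM it was 0.146 ± 0.114 in sham (n = 4), 5.81 ± 0.884 with EP (n = 3), 2.83 ± 2.07 with TPA (n = 4) and 1.77 ± 0.234 with RU486 (n = 4). Differences were 5.67 for EP against sham, -2.98 for TPA and -4.05 for RU486 against EP, with exact permutation p values of 0.0571, 0.114 and 0.0571 (adjusted 0.137, 0.171 and 0.137). In LP the score was 0.107 ± 0.116, 3.25 ± 0.747, 1.47 ± 0.150 and 1.70 ± 0.223 (n = 4 each). Differences in LP were 3.14 (95% interval 2.00 to 4.07), -1.78 (-2.79 to -0.634) and -1.55 (-2.70 to -0.418), each with an exact p of 0.0286, the smallest possible, and an adjusted p of 0.114. In MSC they were 0.655 (-0.433 to 1.74), -0.638 (-1.76 to 0.247) and -0.391 (-1.21 to 0.334), with exact p values of 0.114, 0.0857 and 0.2. TPA minus RU486 was 1.06 in LM (-0.352 to 4.39), -0.227 in LP (-0.571 to 0.259) and -0.248 in MSC (-1.11 to 0.472), with exact p values of 0.457, 0.143 and 0.343. Without mouse 332 the LM difference was 0.0267, and that of TPA from EP was -4.02. Scores with an antagonist lay above sham by 2.68 and 1.62 in LM and by 1.36 and 1.59 in LP for TPA and RU486, each with an exact p of 0.0286 (1.65 for LM TPA without mouse 332, exact p 0.0571), and by 0.0169 and 0.265 in MSC (exact p 0.943 and 0.4).

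**Figure D4:**
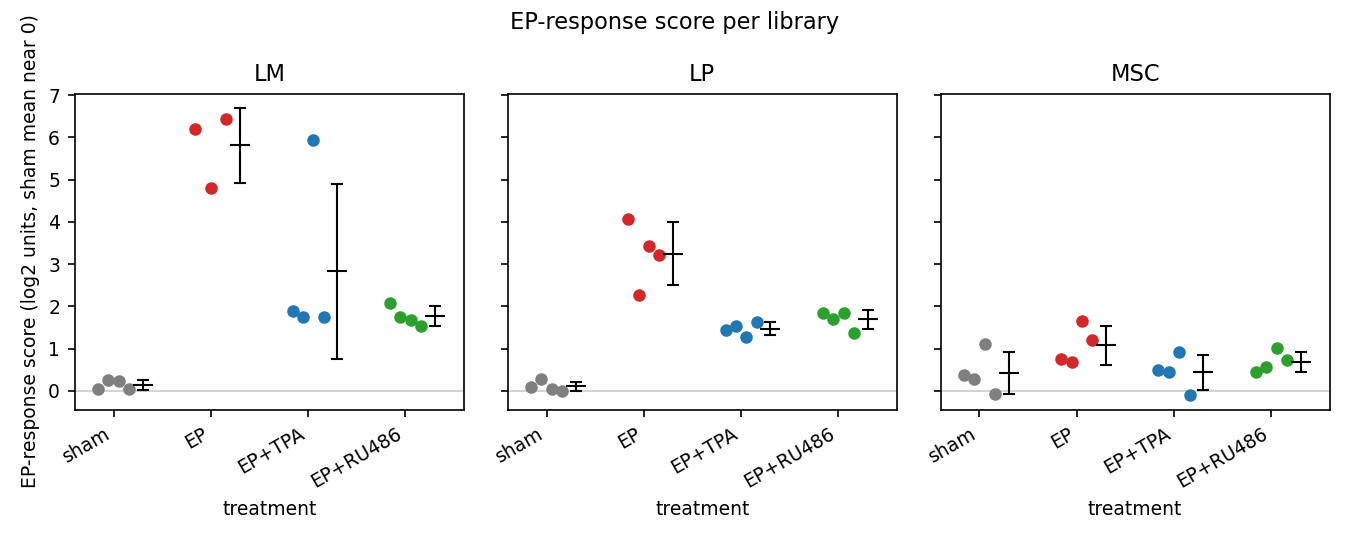
EP-response score of each library by treatment in LM, LP and MSC, in log2 units, with a point per library and bars for mean ± SD. The LM TPA library of mouse 332 has a score of 5.93, and the other LM TPA libraries lie between 1.74 and 1.88.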

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

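All tests of explanations in this part were chosen after the results they address had been seen.

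The score and 5 list values were tested for a library far from the others in each group with 4 libraries. Of these 66 tests 6 met Dixon's criterion, and chance alone meets it in about 1 test in 20. The measures are related, so the tests are not independent. In LM the TPA library of mouse 332 had an EP-response score of 5.93 where the other 3 TPA libraries had 1.74 to 1.88. Its proliferation value was 1.34 against -0.320 to -0.131, and its luminal mature value 0.331 against -1.29 to -1.22. The LM RU486 library of mouse 333 had a basal value of 0.556 against 0.140 to 0.189. In LP the luminal mature value of RU486 mouse 304 was -0.0374 against -0.690 to -0.614. In MSC the endothelial value of sham mouse 326 was -2.92 against 0.874 to 1.19. A test of the difference in EP effect between MSC and LP called 233 genes, but it rested on 1 MSC sham library and called 0 with the mouse as a block in 6 mice and 32 without it, so a difference is not shown.

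Against EP, which had itself lowered progenitor markers (median -2.13), LM had lower luminal mature and higher luminal progenitor transcripts with either antagonist. Neither list passed with the estimated correlation for either drug. Against sham the progenitor medians were 0.00 with TPA (1.12 without mouse 332) and 0.98 with RU486. Action on listed receptor targets alone was argued against, since 8 of 15 luminal mature markers on neither receptor list were lower with RU486 and 5 with TPA. A swap of LM and LP tubes within a mouse was argued against, since the highest luminal mature value among the 5 LP libraries of antagonist mice with both fractions was -0.643, against -0.0549 to 0.484 in LP sham. Progenitor cells in the luminal mature gate stay open, since the share of the 21 progenitor markers on neither receptor list with a fold above 0, 90.5% with both drugs, restates the pattern and decides nothing, and endothelial markers had it in 20 of 20 (medians 0.633 and 0.817) and basal markers in 25 and 26 of 30. A change of state within luminal mature cells, which was not tested, stays open as well. In LP the medians of progenitor markers against EP were 1.30 and 1.23. Krt18 in LM, chosen after its values were seen, was lower with RU486 (574 ± 456) than in sham (2935 ± 518, n = 4 each). It was already below sham with EP (1335 ± 1055, n = 3) and was not below EP with TPA (1746 ± 1085, n = 4). Krt18 therefore does not set both drugs apart from EP. Prom1 in LM was 13.8 to 32.6 with EP, 4.75 to 6.76 with TPA and 5.54 to 8.18 with RU486. Means in the same order were 209, 71.8 and 60.9 for Ly6a, 2.62, 7.79 and 10.63 for Itga2, and 11.91, 20.03 and 27.41 for Elf5. For Ly6a, Itga2 and Elf5 libraries overlapped between TPA and EP but not between RU486 and EP. Kit (42.5, 38.9 and 61.4) overlapped for both. These genes were picked after their values were seen, and both open causes could move them, so they decide nothing.

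The LM TPA library of mouse 332 lay near the EP libraries in its score. A swap with an EP library was argued against, since the lowest score among the LM EP libraries was 4.80, above the 1.88 of the highest other TPA library. A single wrong treatment label cannot be told apart from a weak response of that mouse, since mouse 332 has no library of another fraction. Of 2220 genes changed between TPA and EP without it, 79.2% lay nearer the EP mean, but its luminal mature value (0.331) was below the 1.07 to 2.11 of EP, and Prlr (27.5), Foxa1 (3.31), Wnt4 (6.14) and Pgr (0.695) were below the lowest EP library (89.2, 12.4, 10.2 and 1.45). Fkbp5 and Prom1 were at most 9.75 and 6.76 in every LM TPA library, mouse 332 included, against at least 17.9 and 13.8 with EP. These genes were picked after their values were seen, and most of the 2220 genes went the other way. The library was kept, and without it the score of TPA lay 1.65 above sham and at -4.02 from EP.

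In MSC proliferation genes were lower with either antagonist than with EP, and the makeup of the fraction may contribute. With the endothelial value as a term, the adjusted p was 0.0198 for RU486 and the median fold went from -0.914 (median SE 0.271) to -0.800 (SE 0.258), while for TPA the call ended at 0.0628 and the fold went from -0.975 (SE 0.276) to -0.902 (SE 0.263). The written criterion was that the list keep its call with that term, which held for RU486 and not for TPA. A rule on the size of the fold was added once the values had been seen, so it is not used here. For RU486 the kept call argues against endothelial cells as the whole cause, as far as a linear term captures them. For TPA the term decides nothing, and endothelial cells stay open. Fewer basal or more luminal cells stay open. Krt14 was under 10 in 4 of 8 antagonist libraries and in 0 of 8 others, and luminal progenitor values were 0.563 and 0.446 above EP. Krt14 is 1 gene, and the basal list value differed from EP by -0.102 with TPA and -0.472 with RU486. Libraries overlapped in both (exact permutation p 0.886 and 0.6), so a lower basal share is not shown by the list. A drug effect on basal cell division stays open too, and over the alternatives tried the adjusted p ran from 0.0117 to 0.112 for TPA and 0.00973 to 0.345 for RU486.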

How the results depend on the processing

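The planned count models and size factors, quality weights by voom, and all comparisons of LM with LP or MSC were not run, since the values are not counts and LM was adjusted apart. Leaving out shallow libraries was not run, since the planned rule needs counts. Rescaling was chosen after unrescaled results were seen; the pseudocount, weights without voom, values not rescaled, endothelial term, MSC subsets and the fit without a block were added after the data were seen. Of the alternatives for counts, lists and scores, 393 kept their direction and stayed near the main value, 67 moved and 5 reversed. The cause was not tested unless stated.

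Fitting the 2 groups compared only, which leaves fewer samples, gave 2 genes for LM TPA against EP, 1173 for LM TPA against sham, 901 for LP TPA against EP, 2045 for LP RU486 against sham and 1 for MSC TPA against EP. Library quality weights without voom gave 4165 in LM for EP against sham, 2421 (1213 higher, 1208 lower, reversed) for TPA and 3286 for RU486 against EP, and 3643 and 5095 against sham. In LP they gave 3166 for TPA against EP and 1471 and 2658 for TPA and RU486 against sham, and in MSC 1087, 155 and 96 for EP against sham and TPA and RU486 against EP, and 7 and 3 against sham. A pseudocount of 0.1 gave 1 gene for LM TPA against RU486. No filter on low values gave 1, 2 and 1 in MSC for EP against sham and TPA and RU486 against EP. A term for the mouse number range gave 17 and 3 in MSC for TPA and RU486 against EP. Without the MSC libraries of set 3 with Krt14 under 10 there was 1 gene for TPA against sham, and with the endothelial term 1 for RU486 against EP.

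Values not rescaled shifted the median of all genes by 0.144 and 0.245 for EP against sham in LM and LP, by -0.134 and -0.141 for TPA and -0.166 and -0.115 for RU486 against EP, by 0.142 for LP RU486 against sham, and in MSC by -0.251, -0.115, -0.143 and -0.199 for TPA and RU486 against EP, TPA against RU486 and TPA against sham. Their calls were 1665 higher and 754 lower, and 3945 and 949, for EP in LM and LP. For TPA against EP they were 167 and 621 in LM and 540 and 2172 in LP, and for RU486 731 and 1685, and 723 and 1963. Calls against sham in LP reversed to 686 (443 higher, 243 lower) with TPA and 1744 (1315 and 429) with RU486, and MSC TPA against EP gave 5. MSC against LP reversed to 8989 (1789 and 7200; median -0.457), and the EP effect differed for 510 (47 and 463; median -0.435). With the mouse as a block in 6 mice, MSC against LP gave 3461 and the EP difference 0 genes, and without the block 3861 and 32. Of the gene lists 2 passed, 85 with the preset correlation, 37 by fry and 0 not rescaled.

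Leaving out each library in turn gave 907 to 2839 genes in LM for EP against sham, 186 to 2220 for TPA against EP (reversed without mouse 332), 1297 to 1598 for RU486 against EP, 0 to 4 between antagonists, 1089 to 2167 for TPA and 1662 to 2387 for RU486 against sham. In LP the ranges were 2847 to 4141, 1340 to 2732, 1656 to 2955, 0 to 0, 333 to 713 and 677 to 1069 in the same order. In MSC they were 0 to 1 for EP against sham, 0 to 17 for TPA against EP and 0 for the others, and 6365 to 7127 for MSC against LP and 153 to 1258 for the EP difference. Scores ranged in LM from 5.36 to 6.17, -4.02 to -2.62, -4.55 to -3.74 and 0.0267 to 1.43 in the order of the first 4 comparisons, in LP from 2.87 to 3.47, -2.11 to -1.50, -1.88 to -1.28 and -0.333 to -0.164, and in MSC from 0.460 to 0.883, -0.799 to -0.443, -0.525 to -0.195 and -0.408 to -0.0679. In these comparisons no score changed sign with another number of genes, pseudocount or scaling, but LM EP against sham was 7.01 with 50 and 4.48 with 200 genes in each direction and RU486 against EP -5.35 and -2.98.

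The MSC proliferation list had adjusted p values for TPA and RU486 against EP of 0.111 and 0.345 with the 2 groups only, 0.0734 and 0.0836 not rescaled, 0.112 and 0.147 in set 3 only, 0.0522 and 0.0654 without the low Krt14 libraries, 0.0628 and 0.0198 with the endothelial term, and 0.0584 and 0.0430 without EP 327 and sham 326. Leaving out each library gave medians of -1.08 to -0.884 and -0.996 to -0.795. Of the named genes' values past the threshold, 25 of 204 lost their call with 2 groups only, 5 of 18 in the 6 mice both with and without the block, 1 of 223 with a pseudocount of 0.1 and 0 of 222 not rescaled, and no value changed sign. Folds of genes near 0 grew with a pseudocount of 0.1, such as Mki67 in LM from 1.08 to 3.27, by construction. Absolute depth is unknown, so what it limits could not be stated.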

Other observations

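All tests in this part, the splits of the libraries included, were chosen or had their predictions written after the results had been seen. In LP 20 of 26 genes of the immediate early and dissociation stress list, which also respond to the handling of cells, and 7 of 21 glucocorticoid receptor targets were lower with EP than in sham, and 6 and 5 with TPA and 9 and 7 with RU486, though neither list passed with the estimated correlation. In LP interferon response genes were higher with TPA than with RU486 in 12 of 25 adjusted over the list alone and in 0 over all genes, and the list had an adjusted p of 0.147, so this stays a hypothesis. In LM 42 and 47 of 54 ribosomal protein genes were above sham with TPA and RU486 (adjusted p 0.667 and 0.553 with the estimated correlation), while 44 of 48 proliferation genes were below their EP level with RU486, and with TPA 3 of 48 (39 adjusted over the list alone, and 42 of 44 over all genes without mouse 332).

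Other splits of the same libraries were counted for each comparison. In LM only the real split of 35 called as many genes as EP against sham (2329, highest other 318) and RU486 against EP (2141, other 0). The same held for TPA against sham (1924, other 350) and RU486 against sham (2589, other 1). A share of 1 in 35 is the smallest such splits can give, and it was not adjusted over the comparisons. The real labels thus called more genes than any other split, which by itself does not exclude chance. For TPA against EP 3 splits called as many as 539, the highest other 2534, so chance cannot be excluded. That split put TPA mouse 332 with the 3 EP libraries and points to that structure of the samples. For TPA against RU486 the real count was 0, which any split reaches, so the splits decide nothing (35 of 35, highest other 14). In LP only the real split of 35 called as many for EP against sham (3728, other 468) and for TPA and RU486 against EP (2081 and 2398, others 1332 and 440). It was also alone for TPA and RU486 against sham (612 and 1257, others 196 and 0), with the same limit as in LM. For TPA against RU486, with a real count of 0, the splits again decide nothing (highest other 0). The split with 1332 exchanged EP mouse 311 and TPA mouse 336.

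In MSC each real count was 0, which all 35 splits reach by construction, so they decide nothing. The highest other for EP against sham was 2455, from mice 305, 306, 310 and 334 against 311, 322, 326 and 327, a split that points to a structure of the samples. The endothelial values were 0.874 to 1.21 in the former 4 libraries and -4.28 to 0.646 in the latter, and whether other cells cause the structure was not tested. The highest others were 3 and 1 for TPA and RU486 against EP, 1 between the antagonists and 0 against sham. With library weights 9, 3 and 7 of 35 splits called as many as the real 1087, 155 and 96 for EP against sham and TPA and RU486 against EP (highest others 4211, 336 and 2876), so chance cannot be excluded. For MSC against LP 1 of 100 splits, the real one, called as many as 6888 (highest other 4708), with fractions permuted within treatment. That is the smallest share 100 splits can give, and by itself it does not exclude chance.

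Across the 16 MSC libraries 6 relations with the endothelial value were computed by permutation. Treatments were pooled and not held fixed, so a relation may in part restate a difference between treatments. The EP group had the lowest mean endothelial value (-0.966) and the highest mean proliferation value (0.652). With TPA these means were 0.470 and -0.355, and with RU486 0.473 and -0.252. Adipocyte markers rose with it (Pearson r 0.810, p 3e-05, adjusted 0.00018; Spearman rho 0.879, p 5e-05, adjusted 3e-04; r 0.689, p 0.00268 without EP 327 and sham 326; r 0.828 and 0.811 within sets 2 and 3). Pericyte markers had r 0.699 (permutation p 0.00147, adjusted 0.00441), rho 0.806 (p 0.00027, adjusted 0.00081), r 0.648 without both (p 0.0108), and 0.813 and 0.683 within sets. Basal markers had r -0.588 (permutation p 0.0179, adjusted 0.0269), rho -0.712 (p 0.00304, adjusted 0.00608), r -0.403 without both (p 0.152), and -0.702 and -0.566 within sets. Fibroblast markers had r 0.546 (permutation p 0.0272, adjusted 0.0327), rho 0.491 (p 0.0563, adjusted 0.0824), 0.459 without both (p 0.0999), and 0.849 and 0.473 within sets. Proliferation had r -0.582 (permutation p 0.0169, adjusted 0.0269), rho -0.468 (p 0.0687, adjusted 0.0824), -0.316 without both (p 0.268), and -0.313 and -0.639 within sets. Relative depth had r -0.135 (permutation p 0.619, adjusted 0.619), rho -0.0118 (p 0.970), -0.229 without both (p 0.432), and -0.450 and 0.0553 within sets.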
